A study of Eleusine coracana with 4 samples.

How the data were processed

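Leaf RNA of finger millet (Eleusine coracana) was profiled by RNA sequencing in 4 libraries, 1 from each combination of 2 genotypes (CO12 and Trichy 1) with and without salt. Per the labels' protocols, residual DNA was digested, ribosomal RNA was depleted, the remaining RNA was fragmented with RNase III and ligated to adapters, and the barcoded libraries were pooled, amplified by emulsion PCR and sequenced on an Ion Proton instrument. The libraries carry no molecular identifiers that the labels mention, so PCR copies are counted as reads.

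The authors deposited 1 table per library with 55986 features, the same features in the same order and with the same gene lengths in all 4 tables. Per the file headers, each feature has a count of total gene reads and a count of unique gene reads, both whole numbers and not normalized. RPM below is the total gene reads of a feature scaled to a library total of 1000000. The deposited RPKM values equalled RPM divided by the deposited gene length in kilobases, with a largest relative difference of 5.7e-08, and the column of expression values repeated them. RPKM values therefore carry no information beyond the counts and were not tested separately. The aligner, the counting tool, their settings and the genome build are not given in the sources used here. Of the features, 55801 have identifiers of the LOC_Os form, which locus names in the MSU rice annotation also have, and 185 have other identifiers. Chromosome numbers given here are the digits after Os in the identifier. No label or header names the reference, but identifiers of this form point to rice loci. Chromosome numbers and the order of loci therefore need not be those of the finger millet genome. On rice loci, the values depend on how well finger millet transcripts match each locus. A comparison of the same locus between libraries of 1 genotype is less exposed to this than a comparison between loci. Between the genotypes, transcripts that match a locus unequally well would also change its ratio, which was not tested.

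The tables pair no identifier with a gene name, and no annotation was used here. None of the 26 gene lists fixed before the data were examined (salt transport, compatible solutes, photosynthesis, other cell types and others) was matched to features, so no list medians were computed. By the rule fixed at the same time, the text then names for each comparison the 2 identifiers with the highest and the 2 with the lowest log2 ratio, and the 5 most abundant features of each library. Groups of loci by chromosome number were used in place of the gene lists and were chosen after the data were seen.

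Total gene reads were the main measurement. Each library was scaled to its own total, a prior of 0.5 count scaled to depth was added, and the log2 ratio of 2 libraries was taken for features with at least 20 reads in at least 1 of them. Features at least 2-fold apart were counted. Ratios have exact conditional binomial (Clopper-Pearson) 95% intervals, and shares of reads have Wilson 95% intervals. Where a library had 0 reads of a feature, the fold was computed against a floor of 3 counts in that library and is a lower bound that takes the other library's count as exact, so the lower end of the counting interval of the ratio is given beside it. These intervals and bounds cover counting error only. For the difference of the salt response between genotypes, the counting error was taken from the 4 counts, with an interval of 1.96 standard errors. With 1 library per group there is no test of a pair of libraries against replicate spread, and no p-value is given for these comparisons.

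Counting noise was simulated in 100 draws in which both libraries had the same expected share of every feature. All 4 libraries were also thinned binomially to the lowest total, 1831353 reads, in 100 draws. Chromosome medians were placed among 10000 random lists of the same size, matched on mean expression in 10 bins. The difference of the chromosome 10 median from that of the other chromosomes has a 95% bootstrap interval over features from 10000 resamples. On simulated data with 200 features changed 4-fold, drawn from the pooled shares and library sizes of each comparison, 96.4% of the changed features over the floor were at least 2-fold apart in the right direction for CO12 salt against control, over 1025 features, and 3.4% of the unchanged features were also 2-fold apart. For Trichy 1 salt against control, over 727 features, these values were 99.5% and 1.5%. Of the 200 changed features, 169 (CO12) and 197 (Trichy 1) passed the floor in the simulated counts. Features under the floor in the real counts that passed it by noise were not scored. The simulated counts hold counting noise only, with no spread between plants or library preparations, so these percentages do not cover such spread.

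The other settings tried, fixed at the same time, were TMM factors, median-of-ratios factors, no floor and a floor 5 times higher, a prior 5 times higher or lower, a 4-fold threshold, leaving out the 20 most abundant features of any library (26 in all), and keeping only features above 0 in both libraries. Unique gene reads, thinning to equal depth, and median-of-ratios factors over features at the floor were added after the data were seen. An edgeR quasi-likelihood test of salt over both genotypes, also added later, is described in the closing section. Calculations used Python 3.11.15, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, the last for size factors only.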

Results

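Young, fully expanded leaves of finger millet, a C4 cereal, were compared between plants kept well watered and plants given 300 mM NaCl from day 20, at the 4-leaf stage, in the genotypes CO12 and Trichy 1. The series title sets out to relate transcription to the salinity tolerance of a tolerant genotype, and the sample labels do not say which of the 2 that is. Each of the 4 groups had 1 library, so no difference between 2 libraries has a replicate check and their intervals cover counting error only. The libraries held 6272817 (CO12 control), 1831353 (CO12 salt), 3347497 (Trichy 1 control) and 2406821 (Trichy 1 salt) total gene reads, of which 89.6% to 93.1% were unique. Both salt libraries were shallower than both control libraries. Reads were found for 21288, 11675, 15003 and 13374 of the 55986 features in the same order. With all libraries thinned to 1831353 reads, these numbers were 10944, 11675, 10708 and 11451.

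A few loci took almost all reads. The tables do not say what these loci encode, so whether ribosomal RNA left after depletion is among them cannot be told. Chromosome numbers are those in the identifiers. The 20 most abundant features held 96.1% of the reads of CO12 control, 95.9% of CO12 salt, 95.5% of Trichy 1 control and 95.9% of Trichy 1 salt, which left 244857, 75409, 149796 and 98670 reads for all other features. LOC_Os09g01000 on chromosome 9 took 21.3% of the reads (95% interval 21.2% to 21.3%) in CO12 control and 34.4% (34.3% to 34.5%) in CO12 salt. In Trichy 1 it took 29.4% in control and 35.7% in salt. Its neighbour LOC_Os09g00999 took 4.75% and 7.57% in CO12 and 6.15% and 7.31% in Trichy 1. The ratio of reads between these neighbours stayed between 4.47 and 4.88 in the 4 libraries. Together they held 26% of CO12 control, 42.0% of CO12 salt, 35.6% of Trichy 1 control and 43.0% of Trichy 1 salt. LOC_Os03g24640 on chromosome 3 went the other way, with 7.81% in CO12 control against 3.43% in CO12 salt, and 6.59% against 3.29% in Trichy 1. LOC_Os10g21190 on chromosome 10 had a smaller share under salt in CO12, 13.9% against 19.6%. In Trichy 1 it had 14.5% against 15.9%, a difference whose direction turned with TMM factors and with median-of-ratios factors over features at the floor. LOC_Os01g57968 on chromosome 1 held between 24.0% and 28.0%, and LOC_Os04g16722 on chromosome 4 between 5.50% and 6.30%, of each library.

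**Figure D1:**
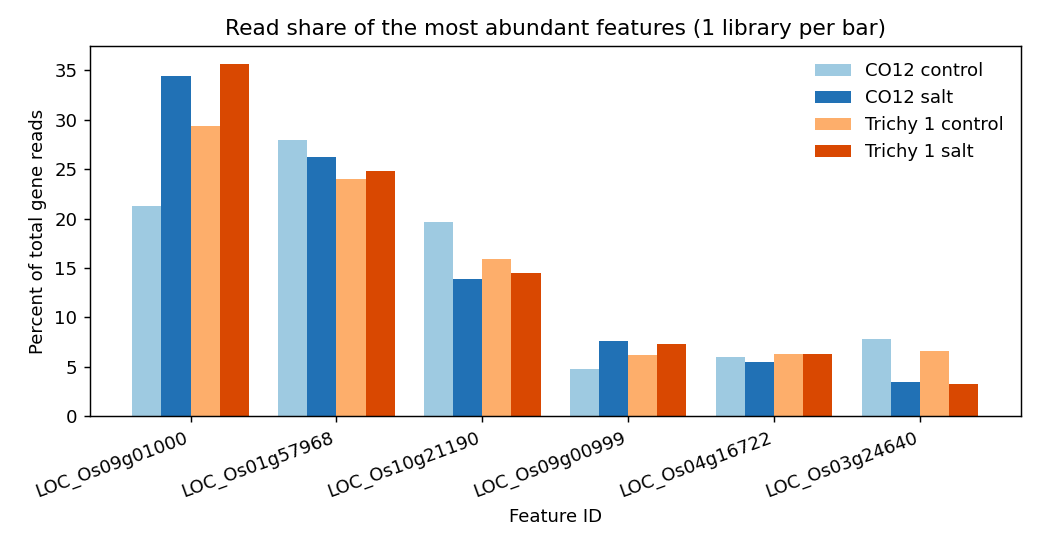
Share of total gene reads (percent, vertical axis) of the 6 features that were among the 5 most abundant in any library, 1 bar per library. LOC_Os09g01000 has a larger share under salt in CO12 (34.4% against 21.3%) and in Trichy 1 (35.7% against 29.4%), and LOC_Os03g24640 a smaller one (3.43% against 7.81% and 3.29% against 6.59%).

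The first comparison asked how the leaf transcriptome of CO12 differed under salt. Of 1025 features with at least 20 reads in either library, 111 were at least 2-fold higher and 196 at least 2-fold lower in the salt library. LOC_Os10g39680 on chromosome 10 (1912 bp) had 12 RPM under salt against 0.48 in control, 22 reads against 3, a ratio of 25.1 (95% interval 7.55 to 131). LOC_Os11g26850 on chromosome 11 (3025 bp) had 25.1 against 1.59 RPM, a ratio of 15.8 (7.84 to 35.0). LOC_Os01g10950 on chromosome 1 (2424 bp) had 37 reads in control and 0 under salt, at least 3.60-fold lower against the floor of 3 counts, with a counting interval from 2.79-fold upward. LOC_Os11g02610 on chromosome 11 (2415 bp) had 34 and 0, at least 3.31-fold lower against that floor, with an interval from 2.55-fold upward. Of the 34 reads of LOC_Os11g02610, 6 were unique. LOC_Os11g26850 was also higher under salt in Trichy 1, with 20.8 against 5.97 RPM. LOC_Os10g39680 had 4 and 2 reads there, too few to tell.

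The interval of the ratio lay wholly beyond 2-fold for 48 features higher and 21 lower under salt in CO12, which compares these libraries and not the conditions. The split between directions depended on depth. Counting noise alone, at these depths, put 55.7 features at least 2-fold lower and 5.9 higher on average. With all libraries at the same total, 98.2 features were higher and 65.9 lower on average, out of 519. With TMM factors the split was 130 higher and 173 lower, with median-of-ratios factors 50 and 377, with unique reads 63 and 190, and without the most abundant features 98 and 210.

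The same question in Trichy 1 gave 85 features at least 2-fold higher and 125 lower under salt, of 727 over the floor. LOC_Os01g50030 on chromosome 1 (4776 bp) had 13.3 RPM under salt against 0.30 in control, 32 reads against 1, a ratio of 44.5 (95% interval 7.44 to 1812). LOC_Os05g47540 on chromosome 5 (4302 bp) had 25 reads against 1, a ratio of 34.8 (5.69 to 1428). In CO12 these loci had 12 reads under salt against 0, and 17 against 2. Most reads of both were not unique (3 of 32 and 0 of 25 were unique in Trichy 1 salt), so these counts are uncertain where reads matched several loci. LOC_Os03g12700 on chromosome 3 (2241 bp) had 0.42 RPM under salt against 5.97, 1 read against 20, 14.4-fold lower (2.30 to 596). LOC_Os06g02980 on chromosome 6 (991 bp) had 6.23 against 47.5 RPM, 7.62-fold lower (4.48 to 13.9), and 4 of its 159 control reads were unique.

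In Trichy 1, the interval lay wholly beyond 2-fold for 32 features higher and 23 lower under salt. Counting noise alone put 15.8 features 2-fold apart on average, 11.7 lower and 4.1 higher. The median log2 ratio of all features over the floor was -0.25 in Trichy 1 and -0.15 in CO12 when libraries were scaled to their totals. Relative to that median, 113 features were higher and 73 lower in Trichy 1, and 143 higher and 154 lower in CO12. With TMM factors the split in Trichy 1 was 105 higher and 83 lower, with median-of-ratios factors 70 and 173, with the same factors over features at the floor 103 and 94, and without the most abundant features 100 and 93. With unique reads it was 50 and 104, and with the libraries at the same total 66.9 and 85.7.

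Between the genotypes without salt, 78 features were at least 2-fold higher and 95 lower in Trichy 1 than in CO12, of 1034 over the floor. LOC_Os01g57958 on chromosome 1 (638 bp) had 6.27 against 0.80 RPM, a ratio of 7.87 (95% interval 2.89 to 26.7), with 3 of 21 and 1 of 5 reads unique. LOC_Os04g16886 on chromosome 4 (471 bp) had 6.87 against 1.12, a ratio of 6.16 (2.56 to 17), with no unique reads. LOC_Os06g08240 on chromosome 6 (2430 bp) had 3.29 against 45.3 RPM, 13.8-fold lower in Trichy 1 (7.58 to 27.9), and LOC_Os02g14720 on chromosome 2 (6965 bp) had 1 read against 26, 13.9-fold lower (2.28 to 569). LOC_Os06g08240 was also lower in Trichy 1 under salt, 4.99 against 16.9 RPM. LOC_Os02g14720 had 3.74 against 4.37 RPM under salt, 9 reads against 8, too few to give a direction, and LOC_Os04g16886 had the other order under salt, 5.4 against 14.2. The interval lay wholly beyond 2-fold for 19 features higher and 12 lower. Counting noise alone put 31.0 features 2-fold apart on average, 27.6 lower and 3.4 higher, so the excess of lower features is no sign of a genotype direction. The split was 60 higher and 117 lower with TMM factors, 51 and 136 with median-of-ratios factors, 51 and 136 without the most abundant features, 45 and 86 with unique reads, and 55.1 and 28.3 with the libraries at the same total.

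Between the genotypes under salt, 43 features were at least 2-fold higher and 31 lower in Trichy 1, of 576 over the floor. Counting noise alone gave 12.2 on average, 8.7 higher and 3.5 lower. LOC_Os03g55874 on chromosome 3 (1262 bp) had 87.3 against 12.6 RPM, a ratio of 6.95 (95% interval 4.51 to 11.2), with 15 of its 210 reads in Trichy 1 salt unique. LOC_Os01g10940 on chromosome 1 (495 bp) had 21 reads against 3, a ratio of 5.33 (1.59 to 27.9). LOC_Os10g39680 was 7.23-fold lower in Trichy 1 (2.46 to 28.9), with 4 reads against 22. LOC_Os07g48620 on chromosome 7 (3096 bp) was 6.40-fold lower (3.64 to 12), with 6.23 against 39.9 RPM, and had 12.8 against 20.7 without salt. The interval lay wholly beyond 2-fold for 5 features in each direction. With median-of-ratios factors the split was 59 and 21, with unique reads 28 and 22, and with the libraries at the same total it was 32.3 and 32.7.

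At matched depth, more features separated salt from control than separated the genotypes. With every library thinned to 1831353 reads, 164.1 features on average were at least 2-fold apart between salt and control in CO12 and 152.7 in Trichy 1. Between the genotypes, 83.5 features were 2-fold apart without salt and 65.0 with salt. The lowest of the 100 draws for either salt comparison gave 139 features, and the highest for either genotype comparison gave 99. Counting noise alone gave between 8.1 and 9.6 features. These ranges cover the thinning only, since each comparison rests on 1 library per group.

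**Figure D2:**
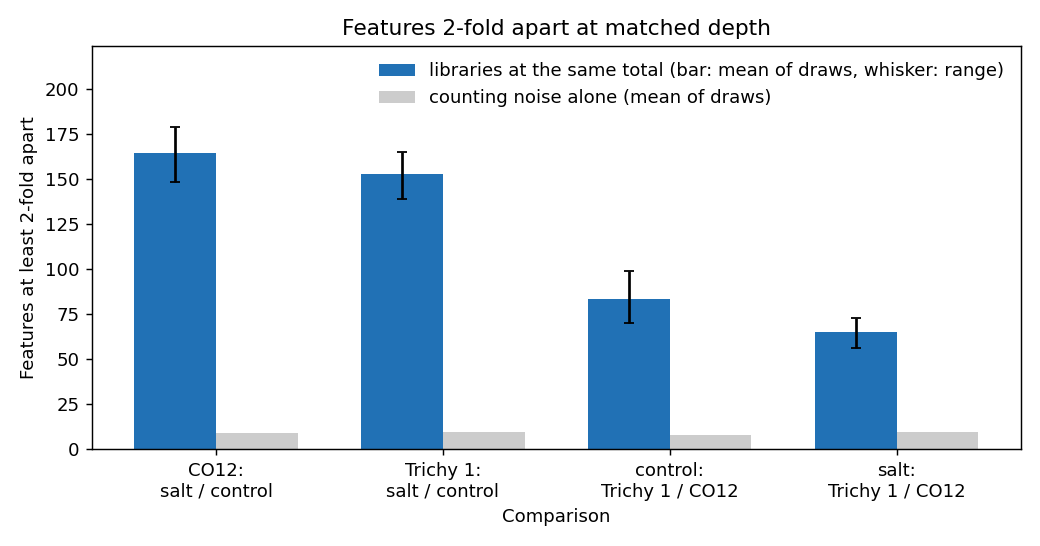
Number of features at least 2-fold apart (vertical axis) in the 4 comparisons, with all libraries thinned to 1831353 reads. Blue bars are means of 100 draws with whiskers from the lowest to the highest draw, and grey bars are the mean under counting noise alone. The salt comparisons (164.1 and 152.7) stand above the genotype comparisons (83.5 and 65.0).

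The design also asks whether the salt response was alike in the genotypes. The salt comparisons share no library. Over the 686 features above the floor in both, the log2 ratios of CO12 and Trichy 1 were correlated across features (Pearson's r = 0.556, Spearman's rho = 0.555), where features are not independent replicates. In both genotypes, 28 features were at least 2-fold higher and 45 at least 2-fold lower under salt, against 8.4 and 16.7 for independent lists of these sizes. In opposite directions, 8 features were 2-fold apart, against 24.8. The differences between genotypes without salt and with salt, which also share no library, had r = 0.076 (rho = 0.051) over 544 features.

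**Figure D3:**
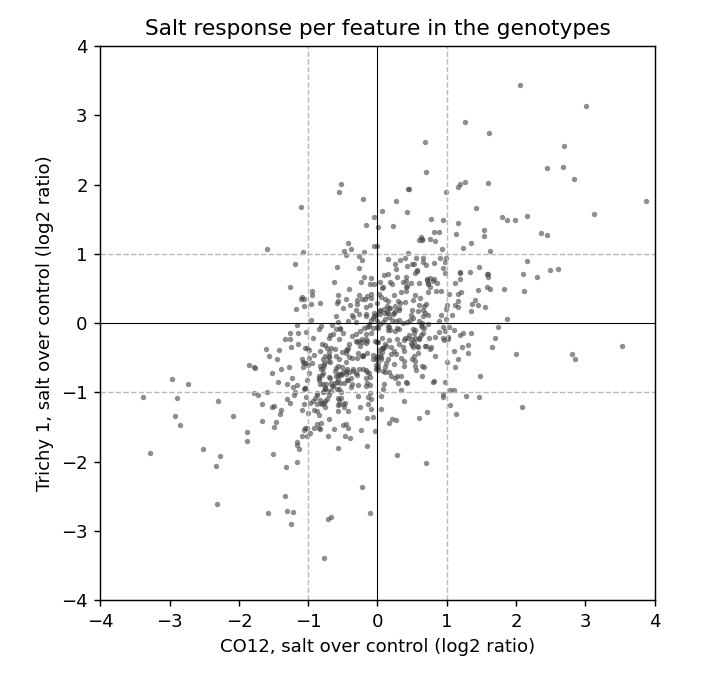
Log2 ratio of salt over control in CO12 (horizontal axis) and Trichy 1 (vertical axis) for the 686 features over the floor in both genotypes. Each point is 1 feature, dashed lines mark 2-fold, and 69.0% of the points have the same sign in both genotypes (r = 0.556).

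The salt response itself differed by at least 2-fold between genotypes for 178 of the 686 features, with 63 higher and 115 lower in Trichy 1 than in CO12. The counting interval of the difference excluded 0 for 247 features and lay beyond 2-fold for 29. LOC_Os07g28160 on chromosome 7 (3641 bp) was lower under salt in CO12, 27.8 against 60.3 RPM, and higher in Trichy 1, 56.5 against 17.6, a log2 difference of 2.78 (95% interval 2.17 to 3.39). LOC_Os12g34550 on chromosome 12 (2543 bp) had a log2 difference of 2.66 (0.98 to 4.34), from 4 against 43 reads in CO12 and 23 against 15 in Trichy 1. The response was higher in CO12 for LOC_Os04g16886, by a log2 difference of -3.87 (-5.39 to -2.35), and for LOC_Os06g50300 on chromosome 6 (6087 bp), by -3.37 (-4.54 to -2.20). LOC_Os06g50300 had 16.9 against 2.23 RPM in CO12 and 8.73 against 12.5 in Trichy 1. LOC_Os04g16886 had no unique reads in any library. The split was 94 higher and 58 lower with median-of-ratios factors and 75 and 73 without the most abundant features. It was 66 and 92 with TMM factors, 44 and 66 with unique reads, and 36.2 and 75.9 with the libraries at the same total.

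Loci grouped by chromosome number differed little in their salt response. Median log2 ratios of the 12 chromosomes ran from -0.36 (chromosome 9) to 0.05 (chromosome 10) in CO12 and from -0.39 (chromosome 3) to 0.00 (chromosome 11) in Trichy 1. None of the 24 medians lay outside the central 95% of matched random lists, with percentiles from 4.3 to 96.4. Between genotypes, the features of chromosome 10 were higher in Trichy 1 without salt, with a median log2 ratio of 0.37 over 70 features, and with salt, with 0.28 over 53. Both medians lay at percentile 99.9 of the random lists, the highest of the 24 percentiles between genotypes. These lists take features as independent, which loci that share reads are not, so the percentiles may be too extreme. Without salt, 16 of the 70 features were at least 2-fold higher and 1 was lower, and chromosome 4 lay at percentile 99.1. With no floor the control median was -0.23. Over features with at least 90% unique reads the medians were 0.08 and 0.33, at percentiles 66.2 and 95.4.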

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

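The features in this part were singled out after their values were seen, and the differences were not tested, since each group has 1 library. Under salt they were higher in one genotype and lower in the other, by at least 2-fold in each and with both counting intervals excluding equality. This held with scaling to totals. TMM factors shifted the log2 ratio of library sizes by -0.179 in Trichy 1. That put LOC_Os04g16748 (-1.058 with totals) and LOC_Os10g38272 (-1.063) under 2-fold there. Median-of-ratios factors shifted it by 0.526 in CO12 and 0.183 in Trichy 1. That put LOC_Os01g58000 (1.128), LOC_Os03g51080 (1.054), LOC_Os04g16748 (1.274) and LOC_Os10g38272 (1.465) under 2-fold in CO12, and LOC_Os12g34550 (1.064) in Trichy 1. The log2 difference, Trichy 1 minus CO12, was 2.78 for LOC_Os07g28160 and 2.66 for LOC_Os12g34550. It was -2.44 for LOC_Os01g58000, -2.23 for LOC_Os03g51080, -2.33 for LOC_Os04g16748, -3.29 for LOC_Os10g21212 and -2.53 for LOC_Os10g38272.

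Of these 7 features, LOC_Os07g28160 had the most reads that matched 1 place only. All of its 378 reads in CO12 control, 51 in CO12 salt, 59 in Trichy 1 control and 136 in Trichy 1 salt were unique. LOC_Os03g51080 had 22 unique of 26 reads in CO12 control and 8 of 9 in Trichy 1 salt. LOC_Os12g34550 had 12 unique of 43 reads in CO12 control and 10 of 23 in Trichy 1 salt. LOC_Os01g58000, LOC_Os04g16748 and LOC_Os10g38272 had 0 unique reads in every library, and LOC_Os10g21212 had at most 1, so these values depend on how reads that match several loci were placed. LOC_Os04g16748 and LOC_Os10g38272 have the same length, 1380 bp. Their counts were close, 110 and 100 in CO12 control, 78 and 81 in CO12 salt, 157 and 175 in Trichy 1 control, and 54 and 60 in Trichy 1 salt. They may therefore not be separate observations.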

How the results depend on the processing

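Scaling, prior and floor choices were planned, and unique reads, thinning and factors over features at the floor were added after the data were seen. The floor and the threshold set the counts of features 2-fold apart. With no floor, counts were 19824 (CO12 salt), 14743 (Trichy 1 salt), 17325 (genotypes in control), 13244 (genotypes under salt) and 8776 (difference of response), and r between the salt responses was 0.073. Most of these features have a few reads. With a floor of 100 reads the counts were 70, 48, 40, 10 and 47, and at 4-fold they were 82, 38, 16, 8 and 31, in the same order. At equal depth the counts were 164.1 for CO12 salt, 83.5 for the genotypes in control and 112.1 for the difference of response, which was 110 with unique reads. The other 51 of 71 such values stayed within 1.5 times the reported count or within the error of r. A scaling shifts all ratios of a comparison alike and leaves r nearly as it was by construction. Median-of-ratios factors rested on 4929 features with a median of 4 reads and put the median log2 ratio at -0.67, -0.43, -0.11 and 0.18 in the 4 comparisons, against -0.15, -0.25, 0.08 and 0.04 with totals and -0.07, -0.07, -0.02 and 0.04 with TMM factors.

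Of the log2 ratios of named features and chromosome 10 medians, 373 stayed within their counting interval (medians within 0.1) and 75 moved. Those 75 include LOC_Os04g16722 for salt in Trichy 1, whose interval included 0 and which was 0.172 with TMM factors and 0.146 with factors over features at the floor. Another 11 changed sign, as follows. With median-of-ratios factors, LOC_Os01g57968 had -0.138 for salt in Trichy 1 and 0.061 between the salt libraries, where LOC_Os09g00999 had 0.095 and LOC_Os03g24640 had 0.086. LOC_Os04g16722 had -0.119 between the controls, and -0.018 with TMM factors. LOC_Os10g21190 had 0.039 for salt in Trichy 1 with TMM factors and 0.013 with factors over features at the floor, where LOC_Os01g57968 had 0.003 for salt in CO12. With unique reads LOC_Os01g57968 had -0.012 for salt in Trichy 1. The chromosome 10 median between controls was -0.23 with no floor. The cause was not tested. With 1 library per group, no replicate could be left out of a group. The labels pair no replicates, and the test with genotype as a block is given among the other observations. Gene list medians were not run.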

Other observations

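The tests in this part were chosen after the comparisons between libraries were seen, apart from TMM scaling and leaving out the most abundant features. The bootstrap intervals for chromosome 10 were added after its medians were seen.

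Taking the genotypes as the replicates of salt, 2 libraries against 2, edgeR's quasi-likelihood test with TMM factors and Benjamini-Hochberg adjustment called 38 of 1066 features at an adjusted p under 0.05, 29 higher and 9 lower under salt. With genotype as a block, 19 were higher and 2 lower, and the values that follow are from that fit. LOC_Os02g41580 had 37 reads under salt against 15 in CO12 and 60 against 9 in Trichy 1, a fitted log2 ratio of 3.25 (edgeR adjusted p = 0.00903). LOC_Os05g47540 had 17 against 2 and 25 against 1, a fitted log2 ratio of 4.93 (edgeR adjusted p = 0.00903), with no unique read in any library. The 2 lower features were LOC_Os04g16770, with a log2 ratio of -1.23 (edgeR adjusted p = 0.035), and LOC_Os01g55540, with -2.00 (edgeR adjusted p = 0.0477) from 6 against 121 and 15 against 75 reads. LOC_Os04g16770 had 35263 reads under salt against 321600 in CO12 and 37043 against 127845 in Trichy 1. Under 10% of its reads over the 4 libraries were unique, so its counts depend on how reads that match several loci were placed. All 4 named features had the same direction in 2 of 2 genotypes. Being called in this fit favours such agreement, so it is no separate support. The blocked test leaves 1 residual degree of freedom, and depth was lower in both salt libraries.

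The 4 libraries can be split into 2 and 2 in 3 ways, and 1 split, salt against control, gave 38 or more features. Splitting them by genotype or by the remaining pairing called 0 features with edgeR, with 13 and 14 at an unadjusted p under 0.05 against 238 for salt. In those fits the salt difference falls into the residual spread, so the 3 splits are not independent. Their common dispersions were 0.1748 (genotype) and 0.1801 (remaining pairing) against 0.0761 for salt. With salt as a block, genotype had 0 features called and 57 at an unadjusted p under 0.05, against 21 and 236 for salt with genotype as a block. With 3 splits a share under 0.05 cannot be reached. On simulated data with a dispersion of 0.1 and 8-fold changes, the blocked test recovered 96.9% of 196 changed features and called 3 unchanged ones, over 1146 features.

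The salt responses of the genotypes went together across the features above the floor in both (r = 0.556). A gap in depth does not account for this, since r was 0.572 with all libraries at the same total (SD over draws 0.015). Reads shared between copies do not either, since r was 0.593 over the 414 features with at least 90% unique reads in every library, nor does gene length, with a partial r of 0.557. A response to salt common to both genotypes may be the source, as a hypothesis. Any handling that differed between the control and the salt plants would give the same pattern and stays open, since the labels give no batches.

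The excess of lower over higher features under salt in CO12 (196 against 111) may come from the control library being the deeper one, because a floor that either library can pass admits more features from the deeper library. At equal depth, lower features made up 40.1% of those 2-fold apart (SD over draws 1.9), 54.9% with unique reads and 44.9% without the most abundant features, against 63.8%, 75.1% and 68.2% at full depth. Totals set by the most abundant features stay open as a further source, since TMM factors lowered the share to 57.1%, within the range named before that test, while leaving these features out raised it. The direction at equal depth depended on the reads counted, with 98.2 higher and 65.9 lower for total reads and 54.5 and 66.3 for unique reads.

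The chromosome 10 median was above that of the other chromosomes in Trichy 1 against CO12 by 0.306 in log2 without salt (95% bootstrap interval 0.1 to 0.519) and by 0.279 with salt (0.077 to 0.372). The resampling and the random lists take features as independent, which loci that share reads are not. The intervals may therefore be too narrow and the percentiles too extreme. Reads shared between copies may account for the difference without salt, which was 0.078 (-0.202 to 0.228) over the 30 features with at least 90% unique reads, at percentile 66.2 of matched random lists. For the one with salt they stay open, since it was 0.319 (0.083 to 0.45) over 16 such features, no smaller than over all features, while its percentile of 95.4 was under the bound named before that test. A run of loci whose identifiers start with LOC_Os10g21, 29 of 70 in the controls and 26 of 53 with salt, stays open as a source: without it the differences were 0.124 (-0.012 to 0.373) and 0.247 (-0.002 to 0.378), at percentiles 84.4 and 97.4. A difference between the genotypes over all loci of this number would also show in features with at least 90% unique reads. Without salt, their interval of -0.202 to 0.228 leaves out 0.306, which argues against a difference of that size there. Over all chromosomes, the median log2 ratio without salt was 0.374 under 10% unique reads, 0.256 at 10% to 90% and -0.001 from 90%. With salt, such a difference stays open.

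For features at adjacent places in the locus order, r between their salt log2 ratios was 0.171 over 106 pairs in CO12. That was near the upper end of the range of 95% of 1000 shuffles, -0.19 to 0.186. In Trichy 1, r was 0.112 over 97 pairs (-0.203 to 0.203). Both values lay within the shuffled range, and with this many pairs a modest likeness of neighbours stays open.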
